A study of Mus musculus with 675 samples.

How the data were processed

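Expression was measured by Smart-seq2 in 675 single cells of male C57BL/6 mice aged 10 weeks, with the tissue label aorta; the series design gives adult males of 8 to 21 weeks. Per the labels' protocols, cells were sorted singly into multi-well plates after dissociation with a skeletal muscle kit and collagenase. The protocol text names the heart as the dissociated organ although the tissue label is aorta, and cells are described by the tissue label. The sort gate and the time of day of collection are not given in the sources used here. Each sample is 1 cell, and Smart-seq2 adds no molecular identifiers.

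The authors deposited counts per gene and cell for 46517 gene identifiers. Per the submitters' processing notes, the tools were bcl2fastq, Bowtie, Bowtie2, featureCounts and Subread with the genome GRCm38 (mm10), and no versions are given. All values were whole numbers, and 0 columns lay outside the labelled cells. Symbols and coordinates came from the GENCODE M21 annotation of GRCm38; 512 identifiers without a symbol held 0.217% of the counts, and 59 symbols were shared by several identifiers. The labels give the plate and the mice of each cell: 367 cells on a plate with a pool of 2 mice (pool A) and 308 cells on another plate with another pool of 2 mice (pool B). Classes of a pool share mice and plate, so the pool was used as a block, and plate and mice are 1 factor. As a check of that pairing, the pool A minus pool B differences correlated across 4924 genes, which are not independent replicates, with r = 0.294 between smooth muscle-like and fibroblast-like cells, 0.194 between smooth muscle-like and endothelial-like cells and 0.106 between fibroblast-like and endothelial-like cells.

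The minimum of 1000 genes and 20000 counts per cell removed 0 cells. In pools A and B the median count was 291756 and 327257 in a smooth muscle-like cell, 163346 and 158676 in a fibroblast-like cell and 240337 and 192763 in an endothelial-like cell. Confidence intervals (exact Clopper-Pearson for shares, exact Poisson for counts, 95%) and floors of 3 counts cover counting error only, since amplified reads without molecular identifiers are not independent molecules. No doublet caller was run. The number of counts per exonic base was compared with depth over smooth muscle-like cells, as the slope of the log count on the log total count per cell. The median slope was 1.47 over 784 genes under 0.1 counts per base, 1.22 over 117 genes from 0.1 to 0.8, and 0.328 over the 8 genes above 0.8, which were AY036118, CT010467.1, Gm42418, Myl9, mt-Rnr2, Acta2, mt-Cytb and Igfbp7. Among these the slope was 0.687 for Myl9, 0.592 for Acta2 and 0.799 for Igfbp7. Whether duplicate reads were removed is not given in the sources used here. A correction for such a ceiling, added after the data were seen, gave 552 called genes for smooth muscle-like against fibroblast-like cells, 440 for smooth muscle-like against endothelial-like cells and 347 for fibroblast-like against endothelial-like cells.

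Genes were divided into 23011 used for clustering, with all markers, and 23469 used for testing, with all lists. The others were assigned by a hash of the symbol, so that a tested gene had not formed the classes. The same cells were clustered and tested, so the split does not make the tests independent of the clustering. A class named by contractile markers such as Myh11 can be higher in other contractile genes for that reason. Another 37 genes, the mitochondrially encoded ones, were in neither set. Counts were scaled to 10000 per cell and logged, and the 2000 most variable clustering genes gave 20 principal components, 15 neighbours and Leiden clusters at resolution 0.5 (scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15, seed 0). Leading genes of a cluster were the 10 with the highest fold of CPM over the mean of the other clusters with 10 CPM added. Of 14 cell types with 81 markers, those with at least 3 markers at 100 CPM were considered for a cluster. It took the type with the most markers among its leading genes, then with the highest mean level relative to the other clusters, and was called by that name with the ending -like. Smooth muscle-like cells were clustered again in the same way, with a minimum of 15 cells per pool for a subcluster. A class needed 10 cells in each pool, which endothelial-like cells (14 and 7) did not reach; a minimum of 5 was added after the data were seen.

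Counts were summed per pool and class, which gave sums of 6729490 to 89441800 counts for smooth muscle-like and fibroblast-like cells and of 1196130 or more where endothelial-like cells took part. Subcluster sums held 5536340 to 64821800 counts. The sums were fitted in edgeR 4.0.16 (R 4.3.3) after filterByExpr with TMM normalization, the pool as a block and the quasi-likelihood F test. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The fit of smooth muscle-like against fibroblast-like cells had 1 residual degree of freedom, and the others 2, and the common biological coefficient of variation was 0.624, 0.776 for fits with endothelial-like cells and 0.659 for subclusters. The SE of a log2 fold change is its size over the square root of the F value. Each subcluster was set against the mean of the others. The genes tested numbered 8791, 7436, 7436 and 8189 for smooth muscle-like against fibroblast-like, smooth muscle-like against endothelial-like, fibroblast-like against endothelial-like cells and subclusters.

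The test was run on simulated data with the depth, dispersion and design of each class comparison and of subcluster 0, not of the other subclusters. In these data, 200 genes with a mean of at least 50 counts were changed by 2-fold, 4-fold or 8-fold. The test recovered 5.97%, 31.8% and 48.5% of the changed genes, with 2 unchanged genes called, for smooth muscle-like against fibroblast-like cells (8514 genes). It recovered 0%, 4.69% and 21.5% with 0 unchanged genes called for smooth muscle-like against endothelial-like cells (7230 genes), and 0%, 2.99% and 19.7% with 0 unchanged genes called for fibroblast-like against endothelial-like cells (7247 genes). For subcluster 0 it recovered 10.4%, 44.8% and 69.7% with 7 unchanged genes called (7916 genes). The simulated means held no difference between pools, and no cells were clustered. The numbers of unchanged genes called therefore do not cover false calls that come from clustering and testing the same cells.

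The 19 gene lists, with 526 of 534 listed genes in the file, cover the contractile apparatus, elastic fibre, collagens, basement membrane, proteoglycans and matricellular proteins, ion channels, vasoactive receptors, cGMP and RhoA signalling, Notch, TGF-beta and BMP, growth factors, developmental transcription factors, Hox genes, immediate early genes, chemokines with cytokines and complement, modulated smooth muscle, lipid handling, endothelial function and the cell cycle. Lists, markers, tests and the naming of clusters from these markers alone were fixed before the data were examined, apart from the additions named as such. The thresholds of the naming rule were not part of that fixed plan. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry. With an estimated correlation, camera has only the 1 or 2 residual degrees of freedom of the fit. It can hardly call a list then, so a lost call does not show that correlation between genes explains it. Named genes are the 5 largest called changes in each direction with at least 50 CPM in both pools of the higher class, the 2 largest called members of each list per direction, the 4 highest members of each list for levels, and the 5 largest pool ratios per direction with at least 100 CPM. Of these, the text gives a selection, and counts of alternative values leave out 1 gene that the rule names. Folds for genes with 1 to 3 counts in the lower class were left out.

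Alternatives were no pool block, DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter and a filter of 10 CPM in 2 sums, cells thinned to 20000 counts, clustering and testing genes exchanged or not separated, resolutions 0.25 and 1.0, cells of at least 2000 genes and 100000 counts (353 and 289 cells), ComBat by pool before clustering, each pool left out, and cell means of CPM. Added after the data were seen were the 5-cell minimum with endothelial-like cells in the fit, the ceiling correction, smooth muscle cluster 0 or 1 alone, fibroblast-like cells of both resolutions, thinning to 51000 counts before clustering, pool ratios without the cell that holds most counts of a gene, and the rule that a cluster with more markers of another type at that level stays unnamed, which changed only a ComBat cluster of 32 cells. Mouse identifiers were left out, and pools were not tested against each other because each side has 1 pool. Figures were drawn with matplotlib 3.10.9.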

Results

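The series is a single-cell inventory of mouse smooth muscle, and the cells analysed here carry the tissue label aorta. Smart-seq2, a plate-based method that amplifies full-length cDNA from single sorted cells, was run on 675 cells from male C57BL/6 mice aged 10 weeks. The labels place 367 cells on a plate from a pool of 2 mice (pool A) and 308 cells on another plate from another pool of 2 mice (pool B). The pool is the replicate, so each comparison had n = 2, and the plate and the mice of a pool are 1 factor. A cell of pool A held 52000 to 608582 counts with a median of 279661, and a cell of pool B 51886 to 713700 with a median of 299297. The median number of genes with a count was 5279 in pool A and 6137 in pool B.

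Smooth muscle-like cells, which carry the contractile proteins of the vessel wall, made up most of both pools. They were 82.8% of pool A (304 of 367 cells; exact 95% interval 78.6 to 86.5%) and 85.1% of pool B (262 of 308; 80.6 to 88.9%). Fibroblast-like cells, the matrix-producing cells led by Dcn, Lum and Pi16, were 13.4% of pool A (49 cells; 10.0 to 17.3%) and 12.7% of pool B (39 cells; 9.16 to 16.9%). Endothelial-like cells, with Cdh5 and Kdr of the vessel lining, were 3.81% of pool A (14 cells; 2.10 to 6.32%) and 2.27% of pool B (7 cells; 0.919 to 4.63%). No test was made between the pools, the intervals cover counting error only, and the gate of the cell sort is not given in the sources used here, although a gate can set such shares. Smooth muscle-like cells fell into cluster 0 and cluster 1. The leading genes of cluster 0 included Pkdcc, Pcdh7 and Mylk4, and those of cluster 1 included Tnnt2, Igfbp2 and Sun2. Cluster 0 held 73.8% of pool A and 20.1% of pool B, and cluster 1 held 8.99% of pool A and 64.9% of pool B. Because Tnnt2 is a marker of cardiac muscle and no smooth muscle marker stood among the 10 leading genes of cluster 0 or of cluster 1, the pools are compared by cluster number. With cells under 2000 genes or 100000 counts left out, smooth muscle-like cells were 89.3% and fibroblast-like cells 6.23% of pool B.

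**Figure D1:**
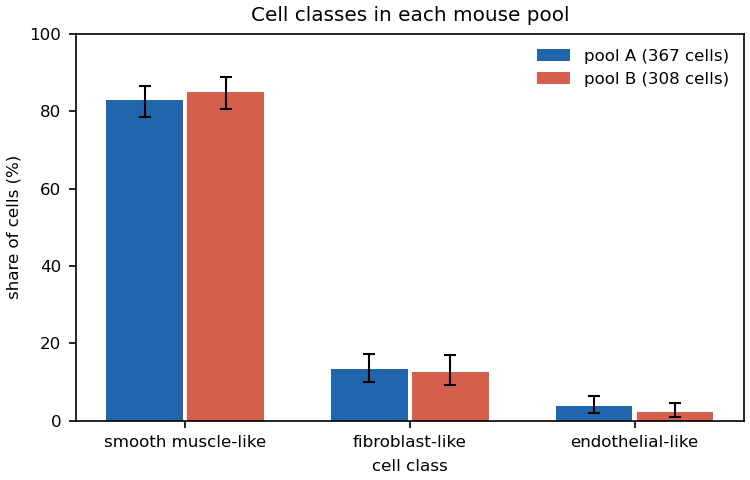
Share of the cells of each pool (percent) in each cell class; bars show pool A (367 cells) and pool B (308 cells), and whiskers the exact 95% binomial interval. Smooth muscle-like cells stand at 82.8% and 85.1%, and the intervals of the pools overlap in each class.

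Levels in smooth muscle-like cells are given for the highest members of the gene lists, as mean CPM (counts scaled to the sum over the class) ± SD over the 2 pools. All 26 genes of the contractile list had at least 10 CPM in both pools. Its highest members were Myl9, the regulatory myosin light chain, at 3753 ± 269, Flna, an actin cross-linker, at 3483 ± 544, and Tpm2, a tropomyosin, at 2746 ± 111. The proteoglycan Bgn stood at 4945 ± 173 and the collagen-binding protein Sparc at 3322 ± 221. Eln, which encodes elastin, reached 2336 ± 524, and the fibrillar collagen genes Col1a2 and Col3a1 reached 1544 ± 64.8 and 1125 ± 211. Col18a1 and Npnt, which encode proteins of the basement membrane, were at 1624 ± 120.5 and 1144 ± 232. Among genes described for modulated smooth muscle, the intermediate filament gene Vim was at 3926 ± 391 and Clu at 1859 ± 46.6. The growth factor list was led by Igfbp7 at 3160 ± 283 and Gas6 at 483 ± 11.4. Myl9 and Igfbp7 are among 8 genes with a median above 0.8 counts per exonic base and cell, and their counts rose with depth with slopes of 0.687 and 0.799, against a median of 1.47 for 784 genes under 0.1 counts per base.

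The lists also cover receptors, channels and signalling. Of the 49 vasoactive receptor genes, 15 had 10 CPM or more in both pools, led by Ramp1, a partner of the receptor for the vasodilator CGRP, at 621 ± 25.6 and the natriuretic peptide receptor Npr1 at 278 ± 61.8. Of 35 ion channel and calcium handling genes, 19 passed that level, led by Kcnmb1, a subunit of the calcium-activated potassium channel, at 529 ± 17.6 and the calcium pump Atp2a2 at 500.3 ± 173. Kcnab1, a potassium channel subunit, had a count in 91.4% and 97.3% of smooth muscle-like cells of pools A and B and in 63.6% of fibroblast-like cells. With cells thinned to 20000 counts these shares were 77.6%, 85.5% and 15.9%. Among signalling genes, Rhoa stood at 628 ± 49.1, the guanylate cyclase subunit Gucy1a1 at 453 ± 16.4, Fstl1 at 1389 ± 144 and the Notch target Heyl at 388 ± 78.9. Myocd, the coactivator that drives smooth muscle genes, was at 633 ± 278 and Osr1 at 422 ± 47.9. Of 39 Hox genes, which mark position along the body axis, 6 reached 10 CPM in both pools, with Hoxb2 at 62.9 ± 4.51 and Hoxa3 at 45.6 ± 8.41. The immediate early genes Fos and Ccn1, which respond within minutes to stimuli that include tissue dissociation, stood at 967 ± 166 and 965 ± 295. The highest chemokine and complement gene was Serping1 at 396 ± 144, the highest lipid handling gene Lrp1 at 391, and the highest cell cycle gene Ccnd2 at 585 ± 117, while 6 of 18 cell cycle genes reached 10 CPM in both pools.

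**Figure D2:**
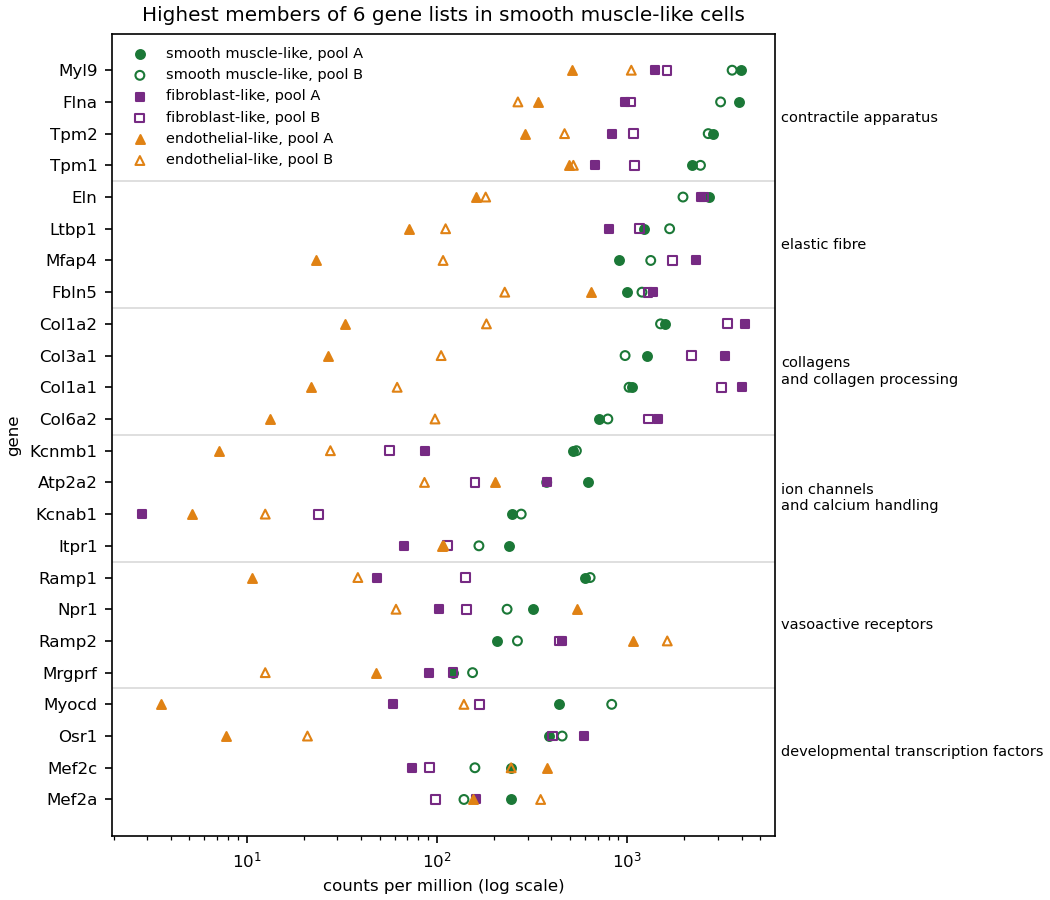
CPM (log axis) of the 4 highest members of 6 gene lists in the 3 cell classes, with filled symbols for pool A and open symbols for pool B. Kcnmb1 stands at 516 and 541 in smooth muscle-like cells and at 86.3 and 56.6 in fibroblast-like cells, whereas Col1a2 is higher in fibroblast-like cells.

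The first comparison set smooth muscle-like cells against fibroblast-like cells of the same pools and asked which genes separate the contractile cells from their matrix-producing neighbours. Smooth muscle-like cells were higher for 22 of 26 genes of the contractile apparatus and for single genes such as Kcnab1, P2rx1 and Myocd. Fibroblast-like cells were higher for 16 of 22 genes of chemokines, cytokines and complement and 15 of 22 collagen genes, with wide differences in C7 and C3. Camera called no list with an estimated correlation between genes (smallest adjusted p = 0.381). With 1 residual degree of freedom, that test could hardly call any list. Of 8791 genes tested, 548 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 205 higher and 343 lower in smooth muscle-like cells, and all 548 had the same sign in both pools, which a call over 2 pools largely requires. Changes are log2 fold changes of smooth muscle-like over fibroblast-like cells ± SE.

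The largest rises among well-covered genes were those of Klhl30 (5.85 ± 0.67, edgeR adjusted p = 0.00319), the ATP-gated channel P2rx1 (5.50 ± 0.73, p = 0.0057), the signalling ligand Wnt16 (5.36 ± 0.72, p = 0.00585), Kcnab1 (4.88 ± 0.71, p = 0.00887) and the kinase Mylk4 (4.53 ± 0.82, p = 0.022). Klhl30 (ENSMUSG00000026308) lies on chromosome 1 at 91351016 to 91362416 of GRCm38 and stood at 76.5 and 84.1 CPM in smooth muscle-like cells and at 0.734 and 2.38 CPM in fibroblast-like cells of pools A and B. The deepest falls among well-covered genes were those of the complement genes C7 (-9.52 ± 0.44, edgeR adjusted p = 0.000122) and C3 (-9.24 ± 0.36, p = 7.89e-05), the peptide receptor Vipr2 (-9.51 ± 0.74, p = 0.000755), the eosinophil attractant Ccl11 (-9.18 ± 0.53, p = 0.00025) and the dipeptidase Dpep1 (-9.11 ± 0.31, p = 7.89e-05). C7 (ENSMUSG00000079105; chromosome 15, 4988762 to 5063740) stood at 0.347 and 0.337 CPM in smooth muscle-like cells and at 346 and 181 CPM in fibroblast-like cells. C3 (ENSMUSG00000024164) lies on chromosome 17 at 57203970 to 57228136, and Dpep1 (ENSMUSG00000019278) on chromosome 8 at 123186242 to 123201812.

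Of 26 contractile genes, 22 were higher in smooth muscle-like cells, none was lower and 4 were not called (23 higher when adjusted over the list alone), with a median of 1.48. Its largest rises were Ldb3, a protein of actin anchorage (3.32 ± 0.38), and Itga8, an integrin of smooth muscle (2.71 ± 0.18; ENSMUSG00000026768; chromosome 2, 12106632 to 12301922). Camera with the preset correlation gave this list an adjusted p = 4.63e-19, and adjusted p = 0.381 with an estimated correlation. Beside this, fibroblast-like cells held the smooth muscle marker Acta2 at 2186 and 3035 CPM, against 6690.4 and 5770.0 in smooth muscle-like cells. In the cGMP and RhoA list, which sets contractile tone, 5 of 24 genes were higher, 1 was lower and 18 were not called (11 higher and 1 lower when adjusted over the list alone). Rgs7bp (2.82 ± 0.39) and Mrvi1, a cGMP kinase substrate (2.03 ± 0.22), were higher, the median was 0.65, and the camera adjusted p = 0.00037 became adjusted p = 0.381 with an estimated correlation. Of 29 channel genes, 3 were higher, 3 lower and 23 not called (6 and 3 when adjusted over the list alone; median 0.78; camera adjusted p = 0.199), with Kcnmb1 higher by 2.91 ± 0.25 and the calcium channel Cacna1g lower (-8.34 ± 0.98).

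Among matrix genes, most collagens were lower in smooth muscle-like cells, the called elastic fibre genes were all lower, and the other matrix lists had called genes in both directions. Of 22 collagen genes, 15 were lower and 7 not called (19 lower when adjusted over the list alone; median -1.28), among them Col5a3 (-6.91 ± 1.17) and Col12a1 (-5.37 ± 0.48). Of 24 proteoglycan and matricellular genes, 12 were lower, 2 higher and 10 not called (16 and 3 when adjusted over the list alone; median -1.19). Cilp was lower (-9.12 ± 1.07), whereas Postn, a matricellular protein, and Sparcl1 were higher (2.18 ± 0.17 and 1.21 ± 0.17). Of 19 elastic fibre genes, 9 were lower and 10 not called (12 lower and 1 higher when adjusted over the list alone; median -0.95). Emilin2 (-7.93 ± 0.72) and Fbln1 (-6.41 ± 0.36) were lower, and Eln, singled out here after its values were seen, did not pass (-0.11 ± 0.17, edgeR adjusted p = 0.812). Camera gave these lists adjusted p = 1.4e-17, 1.93e-09 and 1.93e-09 with the preset correlation, and adjusted p = 0.381 each with an estimated correlation. Of 18 basement membrane genes, 3 were higher, 4 lower and 11 not called (3 and 5 when adjusted over the list alone; camera adjusted p = 0.487). Col18a1 (3.40 ± 0.33) and the integrin ligand Npnt (3.30 ± 0.21) were higher and Lamb1 (-7.31 ± 0.75) and Nid1 (-4.72 ± 0.28) lower, so that the median was 0.19, while the mean was -0.41 and camera pointed to lower values.

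**Figure D3:**
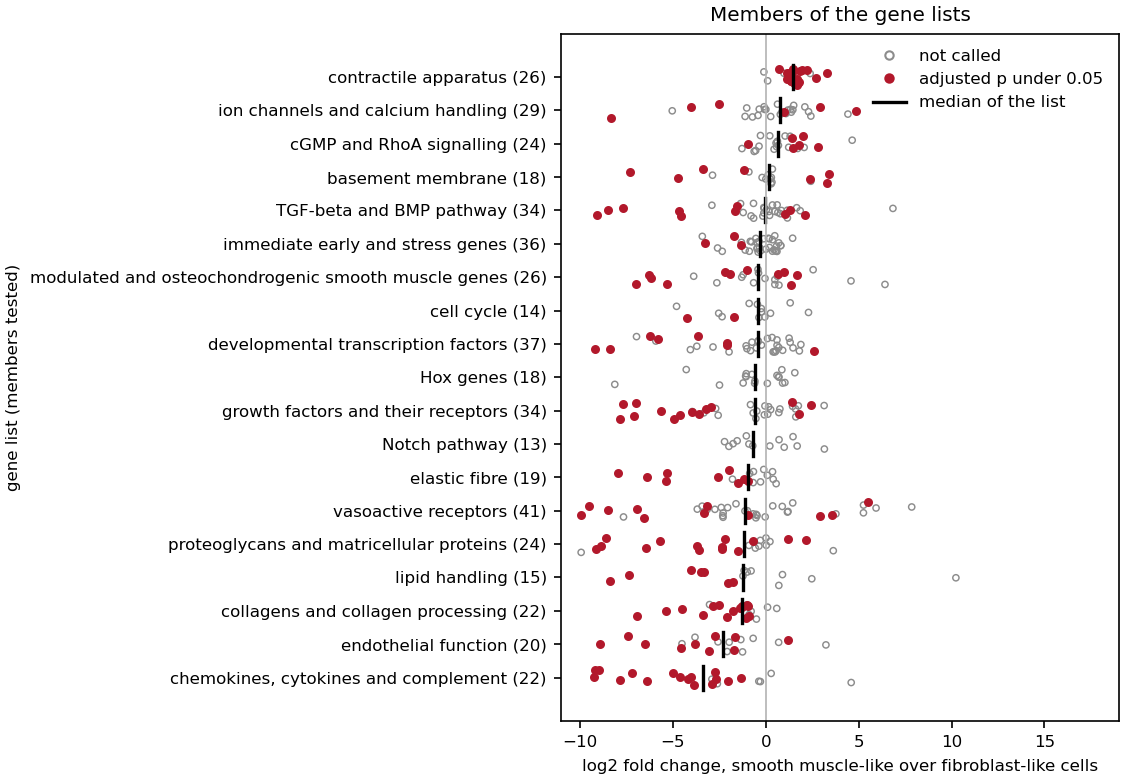
Log2 fold change of smooth muscle-like over fibroblast-like cells for the tested members of 19 gene lists, with filled red points at an adjusted p under 0.05, open grey points above it and a bar at each median. Called contractile genes lie right of 0, and the median of the chemokine, cytokine and complement list lies at -3.39.

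Of 22 chemokine, cytokine and complement genes, 16 were lower in smooth muscle-like cells and 6 not called (18 lower when adjusted over the list alone), with a median of -3.39, camera adjusted p = 1.62e-22 and adjusted p = 0.381 with an estimated correlation. Fry, which asks whether the members move 1 way on balance, called this list (adjusted p = 0.0349) and the proteoglycans (adjusted p = 0.0277). Of 34 growth factor genes, 11 were lower, 3 higher and 20 not called (15 and 5 when adjusted over the list alone; median -0.60). Igfbp6 (-7.84 ± 0.30) and Fgf10 (-7.67 ± 1.16) were lower, and Fgf1 (2.44 ± 0.54) and Pdgfa, a mitogen for mesenchymal cells (1.79 ± 0.32), were higher. Of 41 vasoactive receptors, 8 were lower, 3 higher and 30 not called (11 and 7 when adjusted over the list alone; median -1.12), with the vasopressin receptor Avpr1a lower (-9.94 ± 1.67) and the adrenergic receptor Adra1d higher (3.59 ± 0.73). Of 15 lipid handling genes, 7 were lower and 8 not called (8 lower and 1 higher when adjusted over the list alone; median -1.23), led by Abca8a (-8.39 ± 0.47) and Apod (-7.38 ± 0.70). Camera gave the growth factors adjusted p = 1.26e-05, the receptors 0.00429 and lipid handling 4.38e-06, and each had adjusted p = 0.381 with an estimated correlation. Of 20 genes of endothelial function, 9 were lower, 1 higher and 10 not called (14 and 3 when adjusted over the list alone; median -2.33), with camera adjusted p = 3.68e-09 and adjusted p = 0.396 with an estimated correlation. Procr (-8.91 ± 0.44) was lower and Cav1, a caveolar protein, higher (1.19 ± 0.18), and the endothelial marker Pecam1 stood at 114 and 356 CPM in fibroblast-like cells and 49.6 and 47.3 CPM in smooth muscle-like cells.

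Of 37 developmental transcription factors, 7 were lower, 1 higher and 29 not called (10 and 2 when adjusted over the list alone), with a median of -0.41 that turned to 0.056 at resolution 0.25 and 0.26 with deeper cells alone. The higher gene was Myocd (2.59 ± 0.23; ENSMUSG00000020542; chromosome 11, 65176561 to 65269989), and Meox1 (-9.21 ± 0.87) and Meox2 (-8.39 ± 1.07) were lower. Of 26 genes of modulated smooth muscle, 4 were higher, 7 lower and 15 not called (6 and 8 when adjusted over the list alone). Their median of -0.40 turned to 0.28 at resolution 0.25. Within the pools it was 0.38 (A) and -0.32 (B), as differences of log2 CPM with a prior count, a measure unlike edgeR's fold changes. Clu (1.66 ± 0.23) and the non-muscle myosin Myh10 (1.37 ± 0.20) were higher and the stem cell antigen Ly6a (-6.97 ± 0.41) and Cytl1 (-6.27 ± 0.56) lower. Camera gave the transcription factors adjusted p = 0.0104 and the modulated list adjusted p = 0.0471, and with an estimated correlation the adjusted p = 0.381 and 0.612. Of 34 TGF-beta and BMP genes, 3 were higher, 7 lower and 24 not called (5 and 8 when adjusted over the list alone; median -0.02; camera adjusted p = 0.0717), with the activin subunit Inhba higher (2.11 ± 0.38) and Bmp6 lower (-8.49 ± 1.10), although its change was 4.97 at resolution 0.25. Of 36 immediate early genes, 3 were lower and 33 not called (4 higher and 6 lower when adjusted over the list alone; median -0.31; camera adjusted p = 0.0858), among them Klf4 (-3.25 ± 0.33) and Junb (-1.69 ± 0.24). Of 14 cell cycle genes, Ccnd1 (-4.25 ± 0.59) and Cdkn1c (-1.71 ± 0.31) were lower and 12 not called (2 lower when adjusted over the list alone; median -0.41; camera adjusted p = 0.0606). No gene was called by edgeR among 13 Notch genes (1 higher and 2 lower when adjusted over the list alone; median -0.70; camera adjusted p = 0.473) or 18 Hox genes (0 when adjusted over the list alone; median -0.59; camera adjusted p = 0.318).

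Several of these falls were carried by few of the 88 fibroblast-like cells. A level of 100 CPM was reached in 4 of them by Avpr1a and by Bmp6, in 6 by Cilp and by Fgf10, in 9 by Meox1, in 10 by Meox2 and by Col5a3, in 11 by Cacna1g and by Procr and in 15 by Vipr2. The highest cell held 59.4% of the class's Avpr1a counts, 57.0% of Cilp, 49.5% of Fgf10 and 45.2% of Bmp6. Among the largest rises, 100 CPM was reached in 75 of 566 smooth muscle-like cells by P2rx1, 109 by Wnt16 and 138 by Klhl30. Kcnab1 reached it in 407 and Mylk4 in 351. The highest smooth muscle-like cell held 5.61% of the P2rx1 counts.

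The fibroblast-like cluster was mixed. At the finer clustering, 69 of its 88 cells stayed fibroblast-like, and the others were 10 cells named smooth muscle-like and 9 named endothelial-like there, with Rgs5, a gene of mural cells, at 1606 and 3835 CPM, against 18.6 CPM in the 69. With the 69 cells alone, a setting added after the data were seen, 361 genes passed and 338 of the 548 were among them, the contractile median was 2.61, the cGMP and RhoA median 2.21 and the receptor median 0.47. Medians also turned for immediate early genes (0.74, with 4 higher and 1 lower), Notch genes (0.57) and Hox genes (0.098). With the preset correlation, the channel list became called by camera (adjusted p = 0.0125, median 1.34), and the receptor list was no longer called (adjusted p = 0.243). With an estimated correlation, the camera adjusted p of the channel list was 0.457. Rgs5 (-0.94 ± 0.20) and Kcnk3 (-4.05 ± 0.58), called lower over all 88 cells, turned to 4.26 and 3.01. The count of called genes was 302 without the pool block (all 302 among the 548), 199 at the finer clustering, 239 with deeper cells alone, 69 with endothelial-like cells in the fit and 1352 with DESeq2. At the finer clustering, 132 cells named smooth muscle-like by marker levels formed a cluster. Its 10 leading genes held the cardiac markers Myh6, Tnni3 and Tnnt2 and no smooth muscle marker. Of the 566 smooth muscle-like cells, however, 6.01% had a Myh6 count, 7.95% a Tnni3 count and 44.2% a Tnnt2 count. Only 1 of them had 10 or more Myh6 counts, so Myh6 does not describe the 132 cells as a group.

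The second comparison set smooth muscle-like cells against endothelial-like cells, of which pool B held 7. It was therefore run with a minimum of 5 cells per class, chosen after the data were seen, in place of the 10 fixed earlier. Endothelial-like cells were higher for single genes of lipid uptake and vascular growth such as Cd36, Gpihbp1 and Kdr, and smooth muscle-like cells for 18 of 26 contractile genes. Camera called no list with an estimated correlation (smallest adjusted p = 0.309), a test with little power at 2 residual degrees of freedom. Of 7436 genes tested, edgeR called 435, 233 higher and 202 lower in smooth muscle-like cells, and the sign was the same in both pools for all 435, which is no separate evidence. With DESeq2 size factors the split was 183 higher and 240 lower, and the median of all tested genes moved from 0.66 to 0.38.

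Among the largest rises of well-covered genes were the thromboxane receptor Tbxa2r (6.34 ± 0.88, edgeR adjusted p = 0.0141), Tcea3 (6.22 ± 1.10, p = 0.0298), Sema3d (6.11 ± 1.16, p = 0.0381) and the glycine transporter Slc6a9 (6.10 ± 1.17, p = 0.0395). The deepest falls among well-covered genes were Mcf2l (-12.14 ± 0.81, edgeR adjusted p = 0.00304), Sema3g (-12.05 ± 1.33, p = 0.00848), Apol10b (-11.89 ± 1.44, p = 0.0101), Cyyr1 (-11.84 ± 1.84, p = 0.0195) and Grrp1 (-11.82 ± 1.29, p = 0.0122). Of the 21 endothelial-like cells, 6 had Sema3g and 8 had Mcf2l at 100 CPM, and the highest cell held 58.4% of the Sema3g counts and 38.9% of the Mcf2l counts. Of 26 contractile genes, 18 were higher and 8 not called (22 higher when adjusted over the list alone; median 2.84), led by Pdlim3 (5.36 ± 0.50) and Nexn (5.10 ± 0.59). Endothelial-like cells held Acta2 at 1097 and 1940.4 CPM. Of 19 elastic fibre genes, 9 were higher, 1 lower and 9 not called (12 and 1 when adjusted over the list alone), with the elastin cross-linker Loxl1 higher (5.14 ± 0.44) and Fbln2 lower (-5.00 ± 0.45). Their median was 3.17, or 2.44 with members at 0 counts set to their bound. Of 22 collagen genes, 10 were higher and 12 not called (17 higher and 2 lower when adjusted over the list alone; median 3.32), among them Col5a1 (5.24 ± 0.80). Of 23 proteoglycan genes, 8 were higher, 1 lower and 14 not called (11 and 1 when adjusted over the list alone), with a median of 2.72, or 2.18 with members at their bound, and Smoc1 at 5.28 ± 0.45. Of 15 lipid handling genes, 8 were lower and 7 not called (9 lower when adjusted over the list alone; median -3.42). Cd36, a fatty acid transporter (-10.45 ± 0.29; ENSMUSG00000002944; chromosome 5, 17781690 to 17888801), and Gpihbp1, which holds lipoprotein lipase on capillaries (-10.20 ± 0.95), led it. Of 20 endothelial function genes, 10 were lower and 10 not called (12 lower and 1 higher when adjusted over the list alone; median -2.84), among them the guidance receptor Robo4 (-11.48 ± 1.19).

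Of 14 Notch genes, 4 were lower in smooth muscle-like cells and 10 not called (5 lower and 3 higher when adjusted over the list alone; median -2.02), with the ligand Dll4 at -10.80 ± 2.19. Of 36 immediate early genes, 9 were lower and 27 not called (22 lower and 3 higher when adjusted over the list alone; median -1.85), with the flow-responsive factor Klf2 at -4.30 ± 0.46. Of 24 cGMP and RhoA genes, 4 were higher and 20 not called (11 higher when adjusted over the list alone; median 1.85), with Arhgef17 at 4.36 ± 0.47. Single genes of other lists were the VEGF receptor Kdr (-10.99 ± 0.44), the chemokine Cxcl9 (-10.74 ± 0.62), Bmpr1a (5.95 ± 0.72) and Foxc2 (6.06 ± 0.93). Camera with the preset correlation called 9 of the 19 lists, 5 higher and 4 lower, of which 0 held with an estimated correlation, and fry called 6. Calls numbered 783 without the filter on low counts, 235 at the finer clustering, 250 with deeper cells alone and 1746 with DESeq2. The finer clustering added 9 cells of the fibroblast-like cluster with Pecam1 at 7.91 CPM to the endothelial-like class, and Col14a1 (4.79 ± 0.61) turned to -1.06.

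The third comparison set fibroblast-like against endothelial-like cells, with the same minimum of 5 cells. Fibroblast-like cells were higher for 16 of 22 collagen genes and for single genes such as Fmod and Fbln1, and endothelial-like cells for single genes such as Kdr and Gpihbp1. Camera called no list with an estimated correlation (smallest adjusted p = 0.307), again with 2 residual degrees of freedom and little power. Of 7436 genes, edgeR called 344, 226 higher and 118 lower in fibroblast-like cells, and the sign was the same in both pools for all 344, which is again no separate evidence. The median of all tested genes was 0.48, and 0.30 with DESeq2 size factors. A fold against a class without a count is a lower bound, set against 3 counts over the class. Lpar1, a lysophosphatidic acid receptor, was at least 360-fold higher in fibroblast-like cells, C4b at least 185-fold, Cxcl16 at least 166-fold, Dact1 at least 145-fold and Gli1, a Hedgehog target, at least 113-fold. In the other direction Rasgrp3 was at least 1238-fold lower, Grrp1 at least 748-fold, Rsad2 at least 625-fold and Car7 at least 599-fold. A level of 100 CPM was reached in 12 of the 88 fibroblast-like cells by Gli1 and in 18 by Cxcl16, and in 6 of the 21 endothelial-like cells by Car7, where 1 cell held 43.8% of the counts.

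Of 22 collagen genes, 16 were higher in fibroblast-like cells and 6 not called (20 higher when adjusted over the list alone; median 4.67), with Col14a1 at 8.22 ± 0.69 (edgeR adjusted p = 0.00631). Of 23 proteoglycan genes, 11 were higher, 1 lower and 11 not called (16 and 1 when adjusted over the list alone; median 5.13), with Fmod at 9.10 ± 0.78, Smoc2 at 8.71 ± 0.48 and Sparcl1 lower (-2.51 ± 0.22). Of 19 elastic fibre genes, 9 were higher and 10 not called (15 higher when adjusted over the list alone; median 3.48), with Fbln1 at 8.84 ± 0.53 and Ltbp2 at 7.13 ± 0.89. Of 22 chemokine and complement genes, 9 were higher, 2 lower and 11 not called (17 and 2 when adjusted over the list alone), with a median of 7.07, or 6.04 with members at 0 counts set to their bound. Of 15 lipid handling genes, 2 were higher, 7 lower and 6 not called (3 and 8 when adjusted over the list alone), with Pparg, a regulator of fat storage, lower (-7.33 ± 0.78) and a median of -3.35, or -1.61 with members at their bound. Of 26 contractile genes, 8 were higher and 18 not called (16 higher when adjusted over the list alone), whereas with the 69 cells that stayed fibroblast-like 0 were higher, 1 was lower and the median was 0.28. Of 36 immediate early genes, 1 was higher, 6 were lower and 29 not called (2 and 16 when adjusted over the list alone; median -1.33). Kdr was lower (-10.96 ± 0.46; ENSMUSG00000062960; chromosome 5, 75932827 to 75978458), as were Robo4 (-8.47 ± 1.08) and the water channel Aqp1 (-3.77 ± 0.22), and Prrx1, a mesenchymal transcription factor, was higher (7.04 ± 0.67). Camera with the preset correlation called 10 lists, 6 higher and 4 lower, of which 0 held with an estimated correlation, and fry called 12. Calls numbered 645 without the filter on low counts, 210 at the finer clustering, 186 with deeper cells alone and 1648 with DESeq2, and the contractile median, 1.47 here, was -1.09 at the finer clustering.

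Smooth muscle-like cells clustered on their own gave 3 subclusters, which followed the pools, and the number of groups changed with the setting. After ComBat, which adjusts for the pool, 3 subclusters held 39.5%, 31.9% and 28.6% of pool A and 45.4%, 29.4% and 25.2% of pool B. With cells thinned to 51000 counts before clustering, 90.8% of pool A lay in 1 group and 77.1% of pool B in another. The values below are for the main setting. Subcluster 0 held 232 cells of pool A and 47 of pool B, subcluster 1 held 54 and 106, and subcluster 2 held 18 and 109. No gene passed in any of the 3 edgeR tests of a subcluster against the mean of the others over 8189 genes. An unadjusted p under 0.05 was reached by 479, 177 and 545 genes for subclusters 0, 1 and 2, and DESeq2 called 41, 5 and 167. The 5 DESeq2 genes of subcluster 1 were named after their values were seen. Vcam1 and Msx2 were higher (2.15 ± 0.49 and 5.30 ± 1.15), and Chml, Pf4 and Cd74 were lower (-4.05 ± 0.92, -6.09 ± 1.22 and -4.49 ± 0.94). Msx2 had 10 or more counts in only 5 of 304 smooth muscle-like cells of pool A and 2 of 262 of pool B. Its change can therefore rest on few cells. For the other genes the number of cells is not given here, so their values may not describe a subcluster as a whole.

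List medians between subclusters were small. No camera call held with an estimated correlation, a test with little power at 2 residual degrees of freedom. The smallest camera adjusted p was then 0.620 for subcluster 0, 0.805 for subcluster 1 and 0.510 for subcluster 2. Basement membrane genes had a median of -0.55 in subcluster 2 against the others (17 not called by edgeR over all genes; 9 lower when adjusted over the list alone; camera adjusted p = 1.17e-07), and collagens a median of -0.37 (5 lower when adjusted over the list alone; camera adjusted p = 0.0011). Elastic fibre genes had a median of -0.20 (4 lower when adjusted over the list alone) and immediate early genes -0.26. In subcluster 0, basement membrane genes had a median of 0.45 (camera adjusted p = 0.000161) and contractile genes 0.15 (5 higher when adjusted over the list alone; camera adjusted p = 0.0283), beside channel genes at 0.29 and cGMP and RhoA genes at 0.27. In subcluster 1, contractile genes had a median of -0.11, elastic fibre genes 0.33 and collagens 0.20.

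Between the pools there was 1 pool on each side, so values are given without a test, within clusters of smooth muscle-like cells and with exact 95% Poisson intervals. In cluster 0 the RNA Gm26917 was 8.50-fold higher in pool B, at 955 CPM (940 to 971) against 112 CPM (110.0 to 115). The clock gene Per1 was 4.48-fold higher in pool B, at 115 CPM (109.9 to 121) against 25.8 CPM (24.6 to 26.9). Furin, a protein convertase, was 3.49-fold higher in pool B. Differences were smaller in cluster 1, with Gm26917 at 156 and 329 CPM and Furin at 23.5 and 33.3 CPM in pools A and B. Fibroblast-like cells had Furin at 88.1 and 44.4 CPM, in the opposite direction. Higher in pool A were Inafm2 (2.46-fold), Ccn5 (2.13-fold), Tmem33 (2.10-fold), the transcription factor Foxc1 (2.09-fold) and Pcmtd1 (2.07-fold). In cluster 1, Inafm2 stood at 52.0 CPM in pool A and 54.2 in pool B and Tmem33 at 77.1 and 103 CPM, so that their difference was not shared. In cluster 1, Bcl6 was 9.26-fold, Per1 8.44-fold and Dbp, a clock output factor, 3.54-fold higher in pool B, followed by Nr4a1 (3.48-fold) and Plod1 (3.11-fold). Of the 33 cells of pool A, 1 cell held 49.6% of the 141 Per1 counts and 1 cell 37.4% of the 131 Bcl6 counts, and without the cell in question the ratios were 16.3 for Per1 and 14.4 for Bcl6. Plod1 stood at 84.3 CPM in pool A and 80.8 CPM in pool B in cluster 0. Higher in pool A were Scd2, a fatty acid desaturase (3.29-fold), Foxc1 (3.05-fold), Ppp2r5a (3.02-fold), Tulp4 (2.89-fold) and Cdc42bpb (2.88-fold, or 2.15-fold without the cell with 28.3% of its pool A counts). In cluster 0, Tulp4 stood at 59.1 and 64.1 CPM and Cdc42bpb at 65.9 and 79.4 CPM in pools A and B, in the opposite direction. Scaf1 and Heg1 were 3.26-fold and 3.05-fold higher in pool B in cluster 0. Their differences were smaller in cluster 1, at 45.6 and 83.2 CPM for Scaf1 and 96.5 and 116 CPM for Heg1 in pools A and B.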

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

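Both tests of why clusters follow pools were chosen only after that pattern was seen. Some gene lists had medians of opposite sign in the 2 pools, a difference between pools that was not tested. These medians are of differences of log2 CPM with a prior count, so they do not match the medians of edgeR's fold changes. For smooth muscle-like against fibroblast-like cells, the Notch median was 0.62 in pool A and -0.18 in pool B, the TGF-beta and BMP median 0.12 and -0.12, the immediate early median 0.028 and -0.14, and the median of modulated smooth muscle genes 0.38 and -0.32. For smooth muscle-like against endothelial-like cells, the basement membrane median was -0.13 in pool A and 0.83 in pool B and the cell cycle median 1.74 and -0.62. For fibroblast-like against endothelial-like cells, the cell cycle median was 2.92 in pool A and -0.61 in pool B, where 7 endothelial-like cells were measured.

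Mitochondrially encoded genes, which took no part in clustering or testing, were a signal outside the comparisons. They held a median of 1.95% of a cell's counts in pool A and 1.79% in pool B.

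The clusters of smooth muscle-like cells followed the pools, with 73.8% of pool A in cluster 0 and 64.9% of pool B in cluster 1. Depth was argued against as the cause: with every cell thinned to 51000 counts before clustering, 84.5% of smooth muscle-like cells still lay in the cluster that held most of their pool. A plate or library batch stays open. The pool A minus pool B differences of smooth muscle-like and fibroblast-like cells correlated across genes with r = 0.294, and since each pool of mice had its own plate, mice and plate cannot be told apart.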

How the results depend on the processing

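Fibroblast-like cells of both resolutions, smooth muscle clusters alone, endothelial-like cells in the fit, and every setting for comparisons with endothelial-like cells were chosen only after the data were seen. Of the alternative counts of called genes, 38 were within 1.5 times the reported count. The 548 genes called between smooth muscle-like and fibroblast-like cells became 302 without a replicate block, 239 with clustering and testing genes exchanged, 314 without their separation, 199 at resolution 1.0, 239 with cells of 2000 genes and 100000 counts, 361 with cluster 0 alone, 335 with cluster 1 alone, 361 with fibroblast-like cells of both resolutions, 69 with endothelial-like cells in the fit and 1352 with DESeq2. At resolution 1.0 a cluster of 132 cells counted as smooth muscle-like had cardiac muscle genes among its leading genes. Only 1 of the 566 smooth muscle-like cells had 10 or more counts of Myh6, the first of these genes. The 435 genes of smooth muscle-like against endothelial-like cells became 783 without a filter, 235 at resolution 1.0, 250 with the stricter cell filter and 1746 with DESeq2. The 344 genes of fibroblast-like against endothelial-like cells became 645, 210, 186 and 1648 in that order. The 0 calls of subclusters 0, 1 and 2 became 41, 5 and 167 with DESeq2, and with cells thinned to 20000 counts 1 for subcluster 1 (Cd74, -8.51) and 3 for subcluster 2 (Cd74, 9.14; Rgs5, -1.60; Hspg2, -1.24), genes named after their values were seen. The number of cells behind the Cd74 values is not given here, so they can rest on few cells. Exchanging the gene sets and the stricter cell filter change which genes or cells enter. For the other settings the cause was not tested.

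The 12, 9, 10, 4, 3 and 4 lists that camera called in the 6 comparisons all became 0 with an estimated correlation. Fry called 2 lists for smooth muscle-like against fibroblast-like cells, 1 for subcluster 0 (Hox genes, adjusted p = 0.0185), 0 for subcluster 1 and 0 for subcluster 2. Without a replicate block 2 lists were called for subcluster 0.

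Of the medians of lists that camera called, 441 alternative values with a test kept their direction and call, 29 lost the call and 9 reversed. With a pool left out there was no test, and 83 kept their direction and 1 reversed. Those values are differences of log2 CPM with a prior count, so the measure changed as well as the pools. Between smooth muscle-like and fibroblast-like cells, vasoactive receptors (-1.12) went to 0.019 without separated genes and 0.47 with fibroblast-like cells of both resolutions. Developmental transcription factors (-0.41) went to 0.056 at resolution 0.25 and 0.26 with the stricter cell filter. Modulated genes (-0.40) went to 0.28 at resolution 0.25. In the other measure they stood at -0.32 without pool A and 0.38 without pool B. Between fibroblast-like and endothelial-like cells, contractile genes (1.47) went to -1.05 with genes exchanged, -1.36 without their separation, -1.09 at resolution 1.0 and -0.31 with the stricter cell filter. Medians of lists that camera did not call are outside these counts; with fibroblast-like cells of both resolutions, immediate early genes (-0.31) went to 0.74, Notch genes (-0.70) to 0.57 and Hox genes (-0.59) to 0.098 between smooth muscle-like and fibroblast-like cells. The cause was not tested.

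Of tested values for named genes, 2127 kept direction and call, 420 lost the call and 32 reversed. With a pool left out, 340 values kept their direction without a test, which a call over 2 pools largely requires, so they are no separate evidence. Between smooth muscle-like and fibroblast-like cells, with genes exchanged, not separated, and at resolution 1.0, Kcnk3 went to 3.98, 3.56 and 4.08, Rgs5 to 4.39, 4.28 and 4.32, and Grem1 to 3.90, 3.50 and 4.62. With fibroblast-like cells of both resolutions Kcnk3 went to 3.01 and Rgs5 to 4.26, since the Rgs5-high cells left the class. At resolution 0.25 Grem1 went to 4.75, Bmp6 to 4.97 and Bmx to 0.19. Between smooth muscle-like and endothelial-like cells, Col14a1 went to -0.86 with genes exchanged, -0.53 without their separation and -1.06 at resolution 1.0, and Ltbp2 to -0.48 with the stricter cell filter. Between fibroblast-like and endothelial-like cells, Nexn went to -1.41, -1.23 and -1.13 and Arhgef17 to -0.83, -1.03 and -0.85 with genes exchanged, not separated, and at resolution 1.0. Without separated genes Pdlim3 went to -1.49, Foxc2 to -0.39 and Procr to -0.85, and Pdlim3 to -0.21 at resolution 1.0. With the stricter cell filter Pdlim3 went to -2.50, Foxc2 to -0.81, Cacna2d1 to -0.22 and Arhgef17 to -0.10. The cause of the other reversals was not tested.

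Of class shares, 27 alternative values moved by less than their interval. These include the shares without the cell filter, which could not move because that filter had removed no cell. In pool B, smooth muscle-like cells went to 89.3% and fibroblast-like cells to 6.23% with the stricter cell filter, which removes cells of low depth, and fibroblast-like cells to 8.44% with ComBat, where a cluster with 4.36% of pool A and 5.19% of pool B was left unnamed. Of levels, 138 values moved by less than 1 SD and 12 by more, whereas of shares of cells with a count 149 moved by more with cells thinned to 20000 counts and 1 did not. A pair of alternatives could not be run. Removing cells with 2 markers of another class left no fibroblast-like or endothelial-like cell. When smooth muscle-like cells were clustered on their own, resolution 0.25 gave a single group, so no subclusters could be compared. Leaving out a pool leaves no residual degrees of freedom, so those settings gave differences of log2 CPM with a prior count, without a test.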

Other observations

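The tests of co-occupied wells and of single rare genes were chosen only after the values were seen. The clock and pericyte tests were set before the values of their further genes were read. Both followed values already seen in these same cells, such as those of Per1, Dbp and Bcl6 or of Vtn and Higd1b. Among smooth muscle-like cells 1 cell of pool B carried several genes of cardiac muscle, with 1856 counts of the myosin gene Myh6, 1289 of Tnnt2, 857 of Myl3, 722 of the giant sarcomere protein gene Ttn and 701 of Tnni3. The same cell had 0 counts of the cardiac genes Nppa, Myl2, Myl7 and Mybpc3, and held the smooth muscle genes Acta2 at 4368 CPM and Myh11 at 87.9 CPM. Tfap2b is a transcription factor of the neural crest. It had 10 or more counts in 5 of 304 smooth muscle-like cells of pool A and 3 of 262 of pool B. At the same threshold of counts, 10 genes were picked for their overlap with Tfap2b in pool A. Of these, Msx2, another crest-related factor, shared 3 of the 5 cells of pool A and 0 of the 3 cells of pool B. The protease gene Prss12 shared 2 and 2. Since the genes were picked on pool A, its overlaps are no test, and 3 cells of pool B are too few for one.

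Several genes of the circadian clock differed between the pools, without a test since each side has 1 pool. Nr1d1, a repressor of the clock, stood at 637 CPM in pool A and 1409.9 CPM in pool B in cluster 0, at 669 and 1205 CPM in cluster 1 and at 515 and 1299 CPM in fibroblast-like cells. Its target Arntl, which peaks at the opposite time, stood at 12.8 and 13.3 CPM in cluster 0, so without the opposite change there, at 29.9 and 4.85 CPM in cluster 1 and at 36.1 and 0.446 CPM in fibroblast-like cells. Of the other antiphase genes in cluster 0, Npas2 (25.5 and 7.45 CPM) and Nfil3 (28.5 and 4.44 CPM) were lower in pool B, and Clock (72.3 and 78.1 CPM) and Cry1 (2.75 and 2.87 CPM) were not.

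Per1 and Dbp were higher in pool B, and a candidate explanation is that the pools were in different phases of the clock. With Per1, Dbp and Bcl6 left out, the median log2 ratio of pool B over pool A of 9 genes in phase with Dbp, minus that of 5 genes in antiphase, was 0.90 in cluster 0 (0.899 as the smallest value), 1.75 in cluster 1 and 2.99 in fibroblast-like cells, all above the 0.5 set for the test. A shift between plates that moves expressed genes alike stays open, since the lower percentile among 10000 random gene sets was 97.4 in cluster 0, within the central 95% of random sets (-0.90 to 0.91). The percentile was 99.99 in cluster 1 and 99.98 in fibroblast-like cells, outside the central 95% of their random sets. The test needed cluster 0 and cluster 1 both outside, so it cannot decide about a shift that would act on a whole plate. Fibroblast-like cells were not part of it, and their Ciart (0 and 6) and Cry1 (0 and 1) counts in pools A and B were near the floor. The time of collection is not given in the sources used here, so the phase remains a hypothesis.

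In cluster 2, 3 of 88 cells (1 of pool A and 2 of pool B) carried Vtn and Higd1b together, each at 100 CPM or more, beside 0 of 566 smooth muscle-like and 0 of 21 endothelial-like cells. Pericytes, the mural cells of capillaries, are a possible explanation: 3 of 6 further pericyte genes were at least 10 times higher than in smooth muscle-like cells, where 4 were needed. Cox4i2 stood at 267 against 20.9 CPM, Colec11 at 990.4 against 3.34 CPM and Steap4 at 384 against 0.376 CPM, whereas Rgs4 (535 against 179 CPM), Kcne4 (1.09 against 40.6 CPM) and P2ry14 (0 against 2.84 CPM) did not reach that ratio. Wells that held a smooth muscle cell as well stay open, since Myh11, Cnn1 and Lmod1 together stood at a median of 0.379 of the median smooth muscle-like cell. The 3 cells had ratios of 0.379, 0.785 and 0.232.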
